A study of Mus musculus with 12 samples.

How the data were processed

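Papillomas from the tail skin of 6 mice were profiled on spotted 2-colour arrays. All mice carried an active form of Sos, a guanine nucleotide exchange factor that switches on Ras, under the keratin 5 promoter, which is active in basal keratinocytes. In 3 mice the epidermis lacked Fos (Fos-deficient, specimens 6, 8 and 9) and in 3 mice the Fos alleles were floxed and intact (Fos-floxed, specimens 2, 3 and 5). Per the labels' protocols, papilloma RNA was isolated with TRIzol, amplified with T7 polymerase and hybridised against a commercial reference RNA pooled from mouse cell lines. Each specimen was hybridised on 2 arrays with the dyes exchanged, which gave 12 arrays. The animal was the replicate, and the 2 arrays of a specimen counted as 1.

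The deposited values are log ratios, taken here as log2 ratios of papilloma over reference RNA, 1 value per probe and array. The authors' normalization, background correction, log base and the reason for empty cells are not given in the sources used here. Base 10 is ruled out by the range, since array maxima reached 7.34. A natural log is not ruled out, and folds printed here hold for base 2. The table held 37632 probes, of which 9046 had no value on any array and 17876 had a value on all 12. Between 20811 and 26490 probes had a value on an array, which is 55.3% to 70.4% of the table. Array medians lay between -0.16 and -0.01. Spot signals and backgrounds were not analysed here. The number of arrays limits the precision, with 3 specimens per group.

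The direction of the ratios had to be settled from the values. All 66 pairs of arrays correlated positively across probes, with Pearson's r between 0.705 and 0.963, and the dye-exchanged pairs of 1 specimen had r between 0.909 and 0.947. The deposited ratios were therefore already turned the same way in both dye orientations, and no sign was flipped, although the design fixed in advance had foreseen a flip. Papilloma over reference is the likely direction. A list of keratinocyte genes chosen in advance had medians between 4.60 and 6.00 on the 12 arrays, and a list of genes typical of the reference cell lines had medians between -1.72 and -0.19.

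Gene symbols came from the array's platform annotation. A single symbol was given for 20879 probes, several for 0 and none for 16753. Of 16964 symbols, 12801 were current in the RefSeq gene table of assembly GRCm38.p6, 4006 were updated through a synonym, 58 matched several genes and 99 matched none. The last 157 kept their old symbol. The files name no genome build, so no coordinates are printed.

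A specimen value was the mean of its 2 arrays, and both had to hold a value. The probes of a gene that were measured in all specimens were averaged. Where no probe of a gene was, the probe measured in most specimens was used, and the lowest probe number decided ties. Probes without a symbol were kept as single features. A feature was tested when at least 2 specimens of each group had a value, which left 18861 features, 12006 of them named genes and 6855 unnamed probes. Of the genes named below, Elovl3, Krt2, Tchh and Tyrp1 had values in 2 Fos-floxed specimens, and Abhd3, Dcn, Krt16, Nrg1, Tchh and Tyrp1 in 2 Fos-deficient specimens. The means of the groups were compared with limma (version 3.58.1, with statmod 1.5.0 in R 4.3.3), lmFit and eBayes, two-sided, as Fos-deficient minus Fos-floxed, with Benjamini-Hochberg adjustment and a threshold of 0.05. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

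Of 35 gene lists written for skin, tumour pathways, other cell types and RNA quality, 33 had at least 5 tested members. They were tested with limma's camera statistic at a preset inter-gene correlation of 0.01 (cameraPR on z-scores of the moderated statistic, which admits genes with missing values), against all other named genes, with Benjamini-Hochberg adjustment over the 33 lists. Camera with an estimated correlation and fry were alternatives, run on genes with complete values. For fry, calls are those of its directional test unless its mixed test is named. The lists, the test, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Fos, Adam17, Trp53, Sos1, Egfr, Krt5 and Krt14 where measured, the 10 genes of each direction with the smallest unadjusted p and the same sign in both dye orientations (used because fewer than 20 features passed), and the members of each list with the smallest unadjusted p, 3 per list or 2 for a cell type list. Trp53 and Sos1 were not among the genes tested. Genes outside the rule are marked as chosen or named after their values were seen.

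The alternatives were median-centred arrays, quantile-normalized arrays, probes measured on all 12 arrays, specimen values from 1 or 2 arrays, probes in place of gene means, each dye orientation alone, all 12 arrays with a dye term and the specimen as a random block, eBayes with trend and robust, array weights, each specimen left out in turn, and a threshold of 0.1. A fit with a covariate for the Y-linked gene Eif2s3y was added after seeing the data. The fit was tested on simulated data for 18861 features with the spreads of this comparison, in 10 runs with 200 changed features each. At a 2-fold change 49.2% of changed features passed the threshold, and at an 8-fold change 91.7%. Of the unchanged features 5.27% had an unadjusted p under 0.05, and a mean of 8.8 per run passed the adjusted threshold. The share that passes depends on the 200 changed features planted and on sample spreads taken as true. These rates need not hold in the real data, where Fos, lower by 7.86-fold, had an adjusted p of 0.183 in limma. A list shifted by 0.4 on the log2 scale was called in 10 of 10 runs. The simulation drew genes independently, so it does not test how correlated genes within a list affect that call.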

Results

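Expression was measured in tail papillomas of 6 mice in which an active Sos transgene drives the Ras-Raf pathway in keratinocytes. Fos, a subunit of the AP-1 transcription factor, was deleted in the epidermis of 3 mice and left intact in 3. Values are log2 ratios against a common reference RNA, each the mean of 2 arrays with exchanged dyes, and differences are Fos-deficient minus Fos-floxed. The number of arrays, 12 from 6 specimens, limits the precision, and the 2 arrays of a specimen count as 1 replicate. The comparison asks which genes depend on epidermal Fos in Ras-driven papillomas. From what is known of the study, tumour cell differentiation, p53 and the membrane protease Adam17 were of interest.

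Fos itself was lower in the Fos-deficient papillomas on every array. The mean log2 ratio was -1.14 ± 0.52 (SD, n = 3) in Fos-floxed specimens and -4.11 ± 0.28 (SD, n = 3) in Fos-deficient specimens. The difference was -2.98 (SE 0.29), or 7.86-fold. Single arrays lay between -1.79 and -0.43 in the Fos-floxed group and between -4.74 and -3.56 in the Fos-deficient group. In limma the adjusted p was 0.183 over all features tested and 0.00117 adjusted over the list alone, that of AP-1 family members. An exact two-sided permutation test over 20 assignments gave p = 0.1, the smallest that 3 specimens against 3 allow. The value rests on 1 probe, and whether it lies in the deleted part of the gene is not known here.

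**Figure D1:**
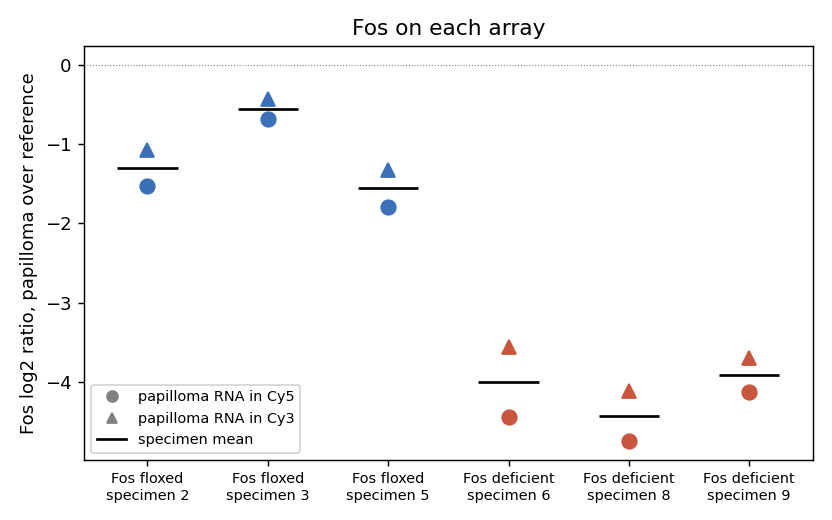
Log2 ratio of Fos, papilloma over reference, on each of the 12 arrays (circles with the papilloma in Cy5, triangles in Cy3), with black bars for specimen means. The Fos-deficient arrays lie between -4.74 and -3.56, all below the Fos-floxed arrays, which lie between -1.79 and -0.43.

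Across all features no difference passed the threshold. In limma 0 of 18861 features had an adjusted p under 0.05, and the smallest adjusted p was 0.183. An unadjusted p under 0.05 was found for 2238 features, 859 higher and 1379 lower in Fos-deficient papillomas, which is 11.9% of those tested. Among 10652 genes with complete values, the groups did not overlap for 20.7%. The mean over all 10 splits of the specimens into 3 and 3 is fixed at 10%. Shares for the other single splits were not computed, so 20.7% is not read as an excess due to the genotype. A model of all 12 arrays with the specimen as a random block called 397 features, 95 higher and 302 lower. It assumes 1 correlation of 0.609 between the arrays of a specimen for all features. It takes its degrees of freedom from the 12 arrays, although the genotype varies only between the 6 specimens. Dye-exchanged arrays thus count partly as replicates, and its features are not called changed here. Of the 10 ways to split the 6 specimens into 3 and 3, a split other than the genotype gave 2800 features with an unadjusted p under 0.05, more than the 2238 of the genotype. Camera called 7 of 33 gene lists for the genotype and up to 12 for another split, and with an estimated correlation it called 0. The lists that camera called are therefore described with both p-values. The 2 runs differ in more than the correlation, the second also using complete genes only. The Adam17 and ErbB list had an estimated correlation of -0.012, below the preset 0.01. Its camera adjusted p still rose from 0.0566 to 0.597. The pair of p-values thus does not measure the effect of correlation alone.

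Among the genes with the smallest unadjusted p, those higher in Fos-deficient papillomas were led by Ltbp3, which binds latent TGF-beta (1.01, SE 0.08), and Cers4, a ceramide synthase of skin (1.47, SE 0.13). Mt2, a metallothionein, differed by 0.99 (SE 0.10) and Tnfrsf18, a receptor of the tumour necrosis factor family, by 1.47 (SE 0.21). Nop10, Acoxl, Tmem218, Abhd3, Stra13 and C1qtnf12 differed by 0.65 to 1.27. Abhd3 had a value in 2 Fos-deficient specimens, and with specimen values from 1 or 2 arrays it differed by 0.74. The symbol Stra13 has been used for several genes. On the lower side stood Ell2, a transcription elongation factor (-1.32, SE 0.12), Dsg3, a desmosomal cadherin of basal keratinocytes (-1.23, SE 0.14), and Kdm5b, a histone demethylase (-0.94, SE 0.10). Xdh, the xanthine dehydrogenase, differed by -1.01 (SE 0.12), and Map3k20, Nploc4, Ptprz1, Tmx3 and Abcg1 by -0.85 to -0.70. Each of these genes had an adjusted p between 0.183 and 0.191 in limma, so none is called changed.

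Genes of the basal keratinocyte layer were lower as a list. Of 22 tested members 17 lay below 0, with a mean difference of -0.69, and camera gave an adjusted p of 7.08e-04, against an adjusted p = 0.597 with an estimated correlation. Members adjusted over the list alone passed in 3 cases, and 0 passed over all genes. These were Col17a1, a collagen of the hemidesmosome (-1.44, SE 0.24), Itgb1, the beta1 integrin (-1.43, SE 0.25), and Lama3, a chain of laminin-332 (-1.44, SE 0.25), each with an adjusted p of 0.0104 over the list alone in limma. Col17a1 differed by -0.72 with the papilloma in Cy5 alone and by -2.16 in Cy3 alone. The keratins of the same layer did not share this difference: Krt14 differed by 0.13 (SE 0.17) and Krt5 by 0.15 (SE 0.09), and the 2 probes of Krt5 had opposite signs, -0.15 and 0.46. Specimen means of the list relative to the Fos-floxed mean lay between -1.005 and -0.46 in the Fos-deficient specimens and between -0.25 and 0.17 in the Fos-floxed specimens.

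Genes of terminal differentiation were lower as a list too. Of 62 tested members 48 lay below 0, with a mean of -0.38 and an adjusted p of 4.58e-04 by camera, against an adjusted p = 0.597 with an estimated correlation. The smallest p belonged to Degs2, which makes phytoceramides (-1.54, SE 0.21, adjusted p of 0.0245 over the list alone in limma), and to the kallikrein proteases Klk12 (-2.14, SE 0.38) and Klk10 (-1.75, SE 0.35). Structural genes of the cornified layers, chosen after their values were seen, went different ways. Krt10 (-0.04, SE 0.12), Krt1 (0.19, SE 0.18), Lor (0.18, SE 0.11) and Flg (-0.13, SE 0.19) were close to 0, and Krt2, with a value in 2 Fos-floxed specimens, was at 4.09 (SE 0.88). Of the Lce genes 9 of 12 lay below 0 (median -0.31) and of the Sprr genes 6 of 10 (median -0.39, from -1.62 to 1.64). With the papilloma in Cy5 alone the list mean was -0.20 and the camera adjusted p 0.139, and with the papilloma in Cy3 alone the mean was -0.61. Over 18 alternatives the adjusted p ranged from 4.63e-07 to 0.597.

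Hair follicle genes were higher as a list, with 21 of 25 members above 0, a mean of 0.93 and an adjusted p of 5.22e-04 by camera, against an adjusted p = 0.614 with an estimated correlation. Krt36 and Tchh, which encode proteins of the hair shaft and inner root sheath, differed by 1.43 (SE 0.27) and 1.62 (SE 0.34), and S100a3, a hair cuticle protein, by 3.14 (SE 0.95). Tchh had a value in 2 specimens of each group, and with specimen values from 1 or 2 arrays its difference was 0.82. Specimens differed widely: relative to the Fos-floxed mean the list lay at 0.71 in specimen 6, 1.47 in specimen 8 and 0.06 in specimen 9, and the Fos-floxed specimens reached 0.07. Without specimen 8 the list mean was 0.49, and with the papilloma in Cy5 alone it was 1.45. Sebaceous gland genes had a mean of 0.65 with 11 of 17 above 0 and did not pass (adjusted p of 0.0791 by camera). With an estimated correlation the adjusted p = 0.614. Over 18 alternatives it ranged from 0.00674 to 0.614, with list means from 0.45 (without Fos-floxed specimen 5) to 0.88, and 6 of them lay under the threshold. Mgst1 (2.63, SE 0.44) and the fatty acid elongases Elovl3 (2.38, SE 0.44) and Elovl6 (2.11, SE 0.42) passed in limma when adjusted over the list alone, each with an adjusted p of 0.0202.

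**Figure D2:**
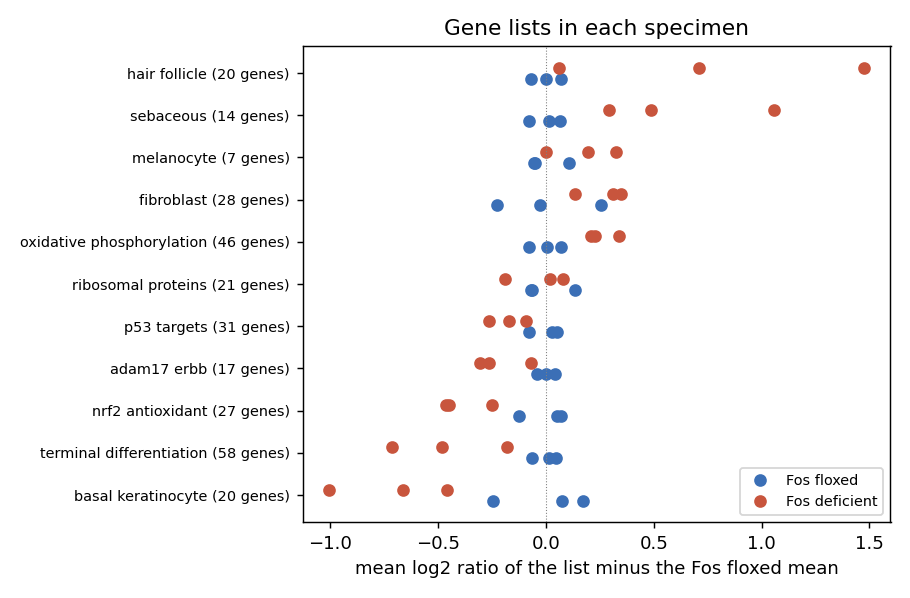
Mean log2 ratio over the genes of each list with complete values, minus the mean of the Fos-floxed specimens, 1 point per specimen (blue Fos-floxed, red Fos-deficient). The groups do not overlap for the basal keratinocyte, terminal differentiation, Nrf2, Adam17 and ErbB, p53 target, oxidative phosphorylation and sebaceous lists. They overlap for the ribosomal protein, fibroblast, melanocyte and hair follicle lists. The hair follicle list ranges from 0.06 to 1.47 among Fos-deficient specimens.

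Oxidative phosphorylation genes were higher by a small amount in nearly all members, 40 of 47, with a mean of 0.26 and an adjusted p of 3.49e-06 by camera, against an adjusted p = 0.597 with an estimated correlation. Ndufs7 of complex I differed by 0.55 (SE 0.09, adjusted p of 0.0477 over the list alone in limma), Cox7a2 of complex IV by 1.07 (SE 0.24) and Sdhb of complex II by 0.55 (SE 0.14). Genes of the Nrf2 antioxidant response were lower, 20 of 29, with a mean of -0.34 and an adjusted p of 0.0206 by camera, against an adjusted p = 0.597 with an estimated correlation. Hmox1, heme oxygenase 1 (-1.24, SE 0.25), and Slc7a11, the cystine transporter (-0.66, SE 0.12), passed in limma when adjusted over the list alone, each with an adjusted p of 0.0412. Nfe2l2, which encodes Nrf2, differed by -1.23 (SE 0.29). The camera call of the Nrf2 list was lost without Fos-floxed specimen 2 (-0.31, adjusted p of 0.0537) and without Fos-deficient specimen 8 (-0.33, adjusted p of 0.0546), and over 18 alternatives the adjusted p ranged from 0.00349 to 0.597.

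The Adam17 and ErbB list and the p53 target list did not pass in camera. In fry's directional test their adjusted p was 0.225 and 0.281. In its mixed test, which ignores direction, it was 0.0024 and 0.0472. Adam17 and ErbB pathway genes had a mean of -0.27 with 13 of 21 below 0 and an adjusted p of 0.0566 by camera. Over the 18 alternatives that adjusted p ranged from 0.0345 to 0.597, and 4 of them lay under the threshold. Adam17 differed by -0.75 (SE 0.35), and its 2 probes gave -0.12 and -1.38. Without Fos-deficient specimen 9 Adam17 was at -0.48. Nrg1, an ErbB ligand, differed by -1.05 (SE 0.14) and Egfr, the EGF receptor, by -0.31 (SE 0.07). Both passed in limma when adjusted over the list alone (adjusted p of 0.0109 and 0.0444). Adam12 passed there as well (-0.87, SE 0.13), but a second probe gave 0.06. A second probe of Nrg1 gave -0.66. The 2 probes averaged for Egfr gave -0.39 (SE 0.17) and -0.23 (SE 0.22), and another Egfr probe gave -0.71 (SE 0.37). Taken singly, these Egfr probes had an unadjusted p of 0.058, 0.335 and 0.117 in limma. The pass of Egfr therefore rests on the averaged value. p53 target genes had a mean of -0.17 with 19 of 32 below 0 and an adjusted p of 0.516 by camera. Ccng1, a cyclin induced by p53, was at -1.13 (SE 0.17, adjusted p of 0.0228 over the list alone in limma). Plk2 was at -1.89 (SE 0.40) and Pmaip1 at -0.70 (SE 0.17), with limma adjusted p of 0.0599 and 0.0690 over the list alone. Cdkn1a, named after its value was seen, differed by -0.41 (SE 0.47).

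Among the lists of other cell types, camera called fibroblasts and melanocytes. Fibroblast genes were higher in 23 of 29 cases, with a mean of 0.32 and an adjusted p of 0.00824 by camera, against an adjusted p = 0.597 with an estimated correlation. Dcn, the proteoglycan decorin, differed by 1.82 (SE 0.51) and Ogn by 0.67 (SE 0.16). All 8 melanocyte genes lay above 0, with a mean of 0.33 and an adjusted p of 0.0241 by camera, against an adjusted p = 0.614 with an estimated correlation. The melanocyte call held under 7 of 18 alternatives, with list means from 0.097 to 0.41 and adjusted p from 0.00827 to 0.614. It was lost with quantile normalization (0.36, adjusted p of 0.0611), on probes measured on all 12 arrays (0.17, adjusted p of 0.0989), with specimen values from 1 or 2 arrays (0.15, adjusted p of 0.148), in Cy3 alone (0.25, adjusted p of 0.126) and with the specimen as a random block (0.30, adjusted p of 0.0562). Leaving out 1 specimen kept it in 2 of 6 cases and lost it without Fos-floxed specimens 3 (0.15) and 5 (0.23) and without Fos-deficient specimens 6 (0.16) and 8 (0.097). Tyrp1, an enzyme of melanin synthesis, had a value in 2 specimens of each group and differed by 1.46 (SE 0.21), or by 0.98 with specimen values from 1 or 2 arrays. The fibroblast call was lost without Fos-floxed specimen 2 (0.21, adjusted p of 0.0537) and without Fos-deficient specimen 8 (0.24, adjusted p of 0.0546), and over 18 alternatives its adjusted p ranged from 1.33e-04 to 0.597. Endothelial genes had a mean of -0.17, smooth muscle and pericyte genes -0.29, macrophage genes -0.01 and skeletal muscle genes 0.02, and none of these lists passed. The smooth muscle and pericyte mean was -0.024 without Fos-deficient specimen 8 and -0.46 without specimen 6, where the list passed. The endothelial mean was -0.76 in specimen 8 relative to the Fos-floxed mean, and with the papilloma in Cy5 alone the list mean had the opposite sign, at 0.30. Without Fos-deficient specimen 8 it was at 0.11.

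Among further lists that did not pass in camera, activated keratinocyte genes had a mean of -0.24 with 17 of 29 below 0. Adjusted over the list alone in limma, 5 members passed as lower and 2 as higher. Specimen means over complete genes did not overlap, at -0.553 to -0.297 in Fos-deficient and -0.062 to 0.071 in Fos-floxed specimens. Gjb6, a gap junction protein (-0.62, SE 0.09), and Il1f9, an interleukin 1 family cytokine (-1.02, SE 0.19), lay lower, and Krt16 lay higher (0.66, SE 0.10). With the papilloma in Cy5 alone Gjb6 was at -0.36, and Krt16 was at 0.44 in the specimens behind its value above. Matrix remodelling genes were split, 17 above and 17 below 0, with Cd44, the hyaluronan receptor, at -1.19 (SE 0.17) and Mmp3, a matrix metalloproteinase, at -1.46 (SE 0.26). Feedback genes of the Ras and ERK pathway had a mean of -0.22, with Spred3 at -1.27 (SE 0.27) and Phlda1 at -1.46 (SE 0.34). Ptgs2, the inducible cyclooxygenase, differed by -2.81 (SE 0.56) in a list of inflammatory cytokines with a mean of 0.12. Proliferation genes were close to 0, with a mean of -0.08 over 62 genes, and ribosomal protein genes had a mean of -0.03. The remaining lists had means of -0.33 (AP-1 family), -0.22 (hypoxia and glycolysis), -0.17 (Notch pathway), -0.12 (B and plasma cells), 0.05 (neutrophils), 0.08 (apoptosis regulators), 0.14 (heat shock), 0.15 (interferon response), 0.17 (T and NK cells), 0.20 (adipocytes), 0.24 (Schwann cells), 0.30 (dendritic and Langerhans cells) and 0.51 (mast cells). The T and NK cell list passed under 6 of 18 alternatives, with means from 0.095 to 0.23 and an adjusted p from 0.0140 to 0.597. The B and plasma cell mean ranged from -0.18 to -0.075. Over the alternatives the dendritic and Langerhans mean ranged from 0.17 to 0.53, the mast cell mean from 0.21 to 0.78, the AP-1 family mean from -0.47 to -0.19 and the activated keratinocyte mean from -0.40 to -0.15. The interferon response mean ranged from 0.041 to 0.28 and passed under 5 alternatives. Matrix remodelling ranged from -0.37 to -0.13, hypoxia and glycolysis from -0.33 to -0.12, Notch from -0.27 to -0.11, proliferation from -0.20 to 0.021 and inflammatory cytokines from -0.13 to 0.26. Mean and median had opposite signs for the macrophage, Notch, B and plasma cell and neutrophil lists.

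**Figure D3:**
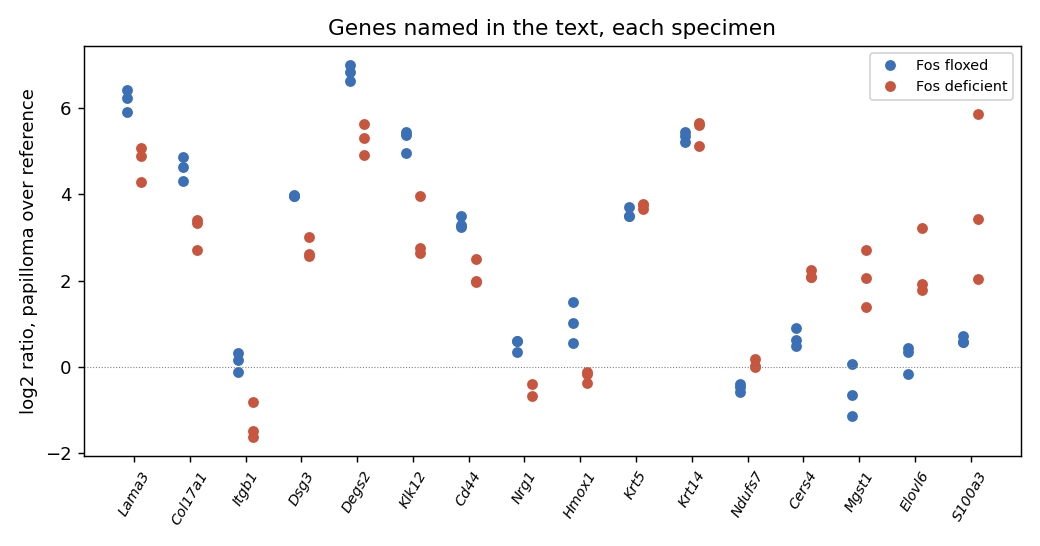
Log2 ratio, papilloma over reference, of 16 genes named in the text, 1 point per specimen (blue Fos-floxed, red Fos-deficient), missing values left out. Lama3, Col17a1 and Itgb1 lie lower in all Fos-deficient specimens, while the Krt14 values of the groups overlap.

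The Y-linked gene Eif2s3y, chosen after its values were seen, was unevenly spread over the groups. Its log2 ratio was -3.39, -2.92 and 2.61 in Fos-floxed specimens 2, 3 and 5 and -2.97, 2.64 and 2.04 in Fos-deficient specimens 6, 8 and 9. Kdm5d, another Y-linked gene named after its values were seen, split the specimens the same way. It was at -0.91, -0.81 and 0.47 in Fos-floxed and at -0.71, 0.21 and 0.20 in Fos-deficient specimens, in the same order. The labels give the sex as unknown, so an uneven share of males is not excluded. With a covariate for an Eif2s3y ratio above 0, chosen after seeing the data, limma called 0 features, with 1763 at an unadjusted p under 0.05, and camera 8 lists. Fos differed by -2.84 in that fit.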

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

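The tests in this part on probe detection and on the 3 gene lists were chosen after the results were seen, as was the count over other splits of features past the adjusted threshold. The counts over other splits of features with an unadjusted p under 0.05 and of gene lists were planned. Probes with a value on 5 or 6 arrays of one group and on at most 1 array of the other could not be tested for a difference. Whether they reflect expression or dim probes that dropped out was not tested. There were 24 such probes for the Fos-deficient group, among them those of the hair keratins Krt34 and Krt35 and of Krtap26-1 and Krtap4-2. For the Fos-floxed group there were 112, among them those of Mmp1a, Grhl2, Dsg1b and Nipal4. A value on all 6 arrays of one group and none of the other was found for 2 probes in the Fos-floxed group, of Nox4 and Prkg2, and for 1 unnamed probe in the Fos-deficient group; a second probe of Nox4 was tested and differed by -0.14 (SE 0.07). These genes were named after their values were seen. Other such probes were of olfactory receptors, Olfr399 for the Fos-deficient and Olfr2 for the Fos-floxed group. Fos-floxed arrays held a mean of 24488 probes with a value (SD 1593, 6 arrays) and Fos-deficient arrays 23202 (SD 1920, 6 arrays). With the papilloma in Cy3, Fos-deficient arrays held 20811 to 22255 and Fos-floxed arrays 23266 to 25287. Both directions together made 136 probes for the genotype split, and at most 96 for any of the other splits of the specimens into 3 and 3.

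Other splits of the 6 specimens bear on the counts. With 10 splits, a share under 0.05 cannot be reached. The genotype split gave 2238 features at an unadjusted p under 0.05 and the highest of the others 2800, so that 2 of the 10 splits gave as many. That split set Fos-floxed specimens 2 and 3 and Fos-deficient specimen 9 against the rest, which is also how the first principal component, with 52.0% of the variance, ordered the specimens. Specimen 9 lay at -19.05 on it, between the Fos-floxed specimens, and specimen 8 at 52.71. Past the adjusted threshold the genotype gave 0 features and the highest of the others 3, and all 10 splits gave at least 0, which carries no information because no count can be lower. The genotype gave 7 gene lists past the camera threshold and the highest of the others 12, and 7 of the 10 splits gave as many. A preset correlation of 0.01 thus called lists in most splits of these specimens, whatever the genotype.

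The lower values of the basal keratinocyte list in Fos-deficient papillomas may reflect the deletion of Fos or the composition of the specimens. A lower share of keratinocyte RNA would lower all abundant keratinocyte transcripts alike, but Krt14 differed by 0.13 and Krt5 by 0.15, each above the list mean of -0.69 by more than 2 standard errors. Spot saturation, which was not analysed here, could hide a change of such abundant transcripts. Most lists of other cell types had higher means, of which only fibroblasts (0.32) and melanocytes (0.33) passed in camera. Mast cells were at 0.51, dendritic and Langerhans cells at 0.30, Schwann cells at 0.24, adipocytes at 0.20 and T and NK cells at 0.17. Neutrophils (0.05), skeletal muscle (0.02) and macrophages (-0.01) were near 0. Endothelial (-0.17), smooth muscle and pericyte (-0.29) and B and plasma cell genes (-0.12) were lower. Without Fos-deficient specimen 8 the endothelial mean was 0.11 and the smooth muscle and pericyte mean -0.024. The 2 keratins alone therefore do not settle the composition of the specimens. The list shifts were -0.66 and -0.76 in the separate orientations, so the shift did not rest on 1 of them. Within an orientation both groups carry the same dye. A dye bias common to all arrays would cancel there, so these values do not test for it. The genotype, sex, litter or mixed background of the mice, RNA quality, and differences between single papillomas, stay open.

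The higher values of the oxidative phosphorylation list may come from the genotype or from RNA quality. A bias towards short mRNAs would raise ribosomal protein genes, whose mRNAs are short as well. The list exceeded the ribosomal protein genes by 0.29 (SE 0.09 between specimens). That argues against the bias as the whole cause only if the ribosomal protein spots were not saturated. Saturation was not analysed here, and no test of transcript length was run, so the bias is not excluded. Of the lists written for RNA quality, the ribosomal protein genes had a mean of -0.03 and the heat shock genes 0.14, and neither passed (adjusted p of 0.539 and 0.407 by camera). The heat shock means did not overlap, at 0.036 to 0.21 in Fos-deficient and at most 0.027 in Fos-floxed specimens. That shift was 0.14 (SE 0.05 between specimens), so a difference in RNA quality is not excluded. RNA integrity numbers were not analysed here, and other effects of RNA quality stay open.

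The higher values of the hair follicle list may come from the amount of follicle tissue in the pieces taken. Without specimen 8, the specimen with the highest list mean, the shift between specimen means was 0.39 (SE 0.25 between specimens), which is too imprecise to tell a shift shared by the group from 1 rich specimen. Lower detection on Fos-deficient arrays is argued against by a shift of 0.75 on probes measured on all 12 arrays. Sampling of follicles and an effect of the genotype on them cannot be told apart with 3 specimens per group that range from 0.06 to 1.47.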

How the results depend on the processing

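One alternative here, the Eif2s3y covariate, was chosen after seeing the data. Of the named genes, 102 of 107 kept their sign under all alternatives run. Most of them were picked for a small p in these data, and some also for the same sign in both dye orientations. Stable signs were therefore largely fixed by that choice and are not separate evidence. The count of 0 features was kept in limma under every alternative except 2. With the papilloma in Cy3 alone 1 feature passed, an unnamed probe lower by 2.09 on the log2 scale. With 12 arrays and the specimen as a random block 397 features passed, 95 higher and 302 lower, and Fos (-2.98) had an adjusted p of 0.00124, against 0.0953 to 0.639 under the other alternatives. The block model takes its degrees of freedom from 12 arrays, although the genotype varies only between 6 specimens. It thus counts dye-exchanged arrays partly as replicates, so its 397 features are not called changed here. Why the Cy3 arrays alone gave 1 feature was not tested. Leaving out 1 specimen gave 1283 to 3324 features at an unadjusted p under 0.05 and 4 to 11 lists, with 4 lists without Fos-deficient specimen 8 and 11 without specimen 6 or 9. Camera with an estimated correlation and fry's directional test called 0 lists each. Fry's mixed test counts changes of members in either direction. Its adjusted p was 0.0024 for the Adam17 and ErbB list and for the AP-1 family, which holds Fos. It was 0.0252 for basal keratinocytes, activated keratinocytes and skeletal muscle, 0.0357 for Nrf2 and 0.0432 for sebaceous genes. For terminal differentiation, oxidative phosphorylation and p53 targets it was 0.0472. The mixed test was not run on other splits.

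The terminal differentiation list did not pass with the papilloma in Cy5 alone (-0.20), nor with an estimated correlation or fry's directional test (-0.46 on complete genes). The Adam17 and ErbB list passed with median-centred arrays (-0.24), with trend and robust (-0.27), with the Eif2s3y covariate (-0.26) and without specimen 6, within -0.32 to -0.20 when 1 specimen was left out. Of 18 alternatives, 16 kept the basal keratinocyte, hair follicle and oxidative phosphorylation calls, 14 the fibroblast and Nrf2 calls and 7 the melanocyte call. Among lists that did not pass, sebaceous and T and NK cell genes passed under 6 alternatives each, interferon response under 5, mast cells under 4, the AP-1 family and endothelium under 2 and 5 further lists under 1. For these and the next values the cause was not tested.

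Some values changed sign, with none past the threshold in the opposite direction. The macrophage list was 0.0074 with median-centred arrays, 0.040 with quantile normalization, 0.0094 on probes of all 12 arrays, with an estimated correlation and with fry, 0.073 in Cy5 alone, 0.26 with array weights, 0.067 with the covariate and -0.32 to 0.19 with 1 specimen left out. The ribosomal protein list was 0.029 with quantile normalization, 0.057 in Cy5 alone and -0.086 to 0.047 with 1 specimen left out. Proliferation was 0.021 with quantile normalization and 0.0077 with the covariate. With values from 1 or 2 arrays neutrophils were at -0.18, endothelium at 0.033 and skeletal muscle at -0.027, and in Cy5 alone at -0.12, 0.30 and -0.081. With 1 specimen left out they ranged from -0.052 to 0.19, -0.33 to 0.11 and -0.023 to 0.062, and inflammatory cytokines from -0.13 to 0.17. With its negative sign the endothelial list passed in Cy3 alone (-0.38) and without Fos-deficient specimen 6 (-0.33). Single probes of Krt5 (-0.15) and Adam12 (0.062), and Pgk1 (0.093), Rpl8 (0.13) and S100a8 (-0.098) in Cy5 alone, had the opposite sign. Signal over background was not analysed here, so its effect on dim probes is unknown.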

Other observations

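Some of the widest differences lay outside the rule for named genes and were chosen after their values were seen. Krt2, a keratin of the upper epidermis, differed by 4.09 (SE 0.88) on 2 Fos-floxed and 3 Fos-deficient specimens, or by 4.11 with specimen values from 1 or 2 arrays, and Slurp1, a secreted protein of keratinocytes, by 2.85 (SE 0.54). Pdpn, the membrane glycoprotein podoplanin, differed by -2.81 (SE 0.44), Tpbg, the trophoblast glycoprotein, by -2.30 (SE 0.34) and Aqp3, an aquaglyceroporin, by -2.13 (SE 0.60). None passed the threshold, with limma adjusted p between 0.191 and 0.279.

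Of 10 gene families looked at, chosen after seeing the data, kallikreins and hair keratin-associated proteins were the most one-sided. Others were split, such as integrins (9 above and 7 below 0), laminins (4 and 5), matrix metalloproteinases (6 and 8) and fatty acid elongases (3 and 3). Claudins (11 and 2) and Nduf genes (34 and 5) lay mostly above 0, and the Sprr (4 and 6) and Lce genes (3 and 9) more often below. Kallikrein genes lay below 0 in 10 of 10 tested cases, with a median of -0.88, and 7 had an unadjusted p under 0.05. The same 10 lay below 0 with median-centred arrays (median -0.86) and with quantile normalization (median -0.78). Part of them belongs to the terminal differentiation list, so they are not separate evidence. Hair keratin-associated protein genes lay above 0 in 14 of 15 cases under each of these scalings, with a median of 1.01 in the values as deposited. No values by specimen are given here for this family. The hair follicle list, of the same tissue, lay at 1.47 in specimen 8 and 0.06 in specimen 9, so the family may not be separate evidence. Probes of such families can bind near-identical copies, so single members are uncertain.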
